A study of Mus musculus with 6 samples.

How the data were processed

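The series measured polyadenylated RNA in embryoid bodies, the free-floating aggregates in which embryonic stem cells differentiate into derivatives of all germ layers. The cells were mouse E14 embryonic stem cells carrying a green fluorescent reporter for Nkx2-5, a gene of early heart cells. Per the labels, they were kept on mitomycin-treated embryonic fibroblasts with leukemia inhibitory factor and differentiated toward cardiomyocytes in hanging drops without that factor. The embryoid bodies were collected on day 10. There were 3 control libraries and 3 libraries from cells lacking Lmna, the gene of lamins A and C. How the knockout was made, how many knockout clones were used and whether the replicates were separate differentiations are not given in the sources used here. The p-values below therefore measure only the spread between these samples, which may be technical.

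The deposited table held 31367 RefSeq transcript rows under 16185 gene symbols. The counts were deposited by the authors as raw reads per transcript row, per the file headers, and no counting tool is given in the sources used here. STAR, DESeq2, edgeR and the mm10 build are named without role or version, per the submitters' processing notes. Whether counting used strand is also not given, so a gene and an antisense or overlapping neighbour cannot be told apart. Isoforms of a gene stood as separate rows that shared reads, and 7004 symbols had more than 1 row. The smallest summed count of any row was 21, so rows below that level were not in the table. No mitochondrially encoded gene was in the table. A scaled signal was deposited by the authors in columns headed TMM, which equalled the raw count times 1 factor per library. Those factors lay within 0.000299, as a relative difference, of DESeq2 size factors computed here. RPKM columns were deposited by the authors, per the file headers. Only between 1.67% and 1.90% of rows per library had an RPKM that followed their own count and length to within 2%, so these columns were not used as expression. A log2 fold change with its error and a p-value with its adjusted value were deposited by the authors for the knockout against the control, per the file headers.

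From the raw counts, 1 row per gene symbol was kept, that of the highest mean count over the 6 libraries. This choice was made after the table was seen, because summing rows would count shared reads several times. The kept rows summed to between 9711364 and 10856339 reads per library, and all rows to between 19964807 and 22095576. Levels are in CPM, the count per 1000000 reads of these rows. A gene at 1 CPM thus had about 10 reads per library. The low-count filter of edgeR 4.0.16 (R 4.3.3) left 14737 genes and dropped 1448. Counts were scaled by the trimmed mean of M-values, with factors between 0.9955 and 1.005. Each gene was tested with edgeR's two-sided quasi-likelihood test, knockout against control, without a block. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was its size divided by the square root of the quasi-likelihood F. CPM values are given as mean ± SD over 3 libraries, on scaled library sizes.

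The pipeline was tested on simulated data with 200 genes changed. Counts were drawn from the means of the 14737 genes and from the trend of dispersion over expression level, not from each gene's own dispersion. It recovered 72% of genes changed 1.5-fold and 85% of genes changed 2-fold, and 9.77% of its calls were false. That false share lies above the one at which the threshold on adjusted p aims. Only 200 of 14737 genes changed in the simulation, whereas 54.3% of genes passed in the data. The called genes of the data had a median absolute log2 fold change of 0.49, less than a 1.5-fold change. Both shares depend on how many genes change and by how much. They therefore do not carry over to the calls in the data. Replicate libraries differed by more than sampling noise, with a chi-square per degree of freedom between 2.65 and 5.89 for pairs of the same group, so no pair was treated as a duplicate deposit of a library. With 3 libraries per group, an exact permutation test of a single value cannot give a two-sided p below 0.1.

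Before the data were examined, 37 gene lists were written from textbook knowledge, and 36 had at least 3 measured members. For each list the members that rose or fell were counted, with p-values adjusted over all genes and again over the list alone. Lists were compared with all other genes by camera of limma 3.58.1 on voom values, with the correlation between genes preset at 0.01 and, as an alternative, estimated. Fry, also of limma, tested whether the members of a list moved one way on balance. It does not compare them with other genes. Most genes tested in these data passed, so fry can call many lists that do not stand apart. P-values of each list test were adjusted over the 36 lists. Genes are named by a rule also fixed before the data were examined. It takes Lmna, 11 genes of heart, endothelium and pluripotency, and the 10 genes of largest rise and the 10 of largest fall. The last 20 had to pass the test with a mean CPM of at least 5 and groups that did not overlap, and predicted gene models were left out. It also takes up to 4 members of each list with the smallest adjusted p. Any other gene named was chosen after its value was seen.

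Gene positions come from RefSeq on GRCm38, the assembly that mm10 denotes, and exons of Lmna from the GENCODE M21 annotation of the same assembly. A position was found for 16147 of the 16185 kept rows. The alternatives tried were DESeq2 (median-ratio) size factors, upper-quartile factors and no factors, the Wald test of DESeq2 1.42.0, limma-voom, no low-count filter, a mean CPM of at least 1, the replicate number as a block, and leaving out each library. Stricter thresholds were tried for the counts of genes. A change of pseudocount did not apply, because counts were at hand. Alternatives added after the data were seen were the longest transcript per gene, all transcript rows, and leaving out control 2 together with knockout 1.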

Results

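RNA was profiled in day 10 embryoid bodies from control mouse embryonic stem cells and from cells lacking Lmna, with 3 libraries in each group. Lmna encodes lamins A and C, intermediate filament proteins that line the inside of the nuclear envelope. The comparison asks how gene expression in differentiating cells, steered toward heart muscle, differs without lamins A and C. The kept gene rows held 9984754, 9711364 and 9903758 reads in the control libraries and 10856339, 10658392 and 10430403 in the knockout libraries. Correlations of log2 CPM across genes lay between 0.990 and 0.994 within groups and between 0.948 and 0.957 between them. Genes are not independent replicates.

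Lmna itself was 9.75-fold lower in the knockout libraries. Its level was 45.3 ± 1.94 CPM in controls and 4.66 ± 1.78 CPM in knockouts (mean ± SD, n = 3 each), a log2 fold change of -3.28 with an SE of 0.16 (edgeR adjusted p = 2.04e-08). The gene lies on the minus strand of chromosome 3 at 88481148 to 88509932 (GRCm38), and the kept row (NM_001002011) is the lamin A transcript of 12 exons. That row held 475, 426 and 441 reads in the controls and 45, 34 and 69 in the knockouts. The lamin C and lamin C2 transcripts share exons 2 to 9 and differ mainly in where they start. Lamin C begins with an exon of 560 bp at 88502748 to 88503307, and lamin C2 with an exon of 76 bp at 88493237 to 88493312, which lies within an intron of the lamin A and C transcripts. The lamin C row exceeded the lamin C2 row by 114, 91 and 107 reads in the controls and by 0 reads in each knockout library. If that excess is taken as a direct count, 0 over the 3 knockout libraries allows up to 0.891% of the control level (3 counts, counting error only). Reads of the lamin C2 row, which leaves out the exon of 560 bp, remained at 14.3% of the control level in the knockouts (exact Poisson 95% interval 11.7% to 17.4%). The interval covers counting error only and pools knockout libraries that held 36, 27 and 54 reads of that row.

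**Figure D1:**
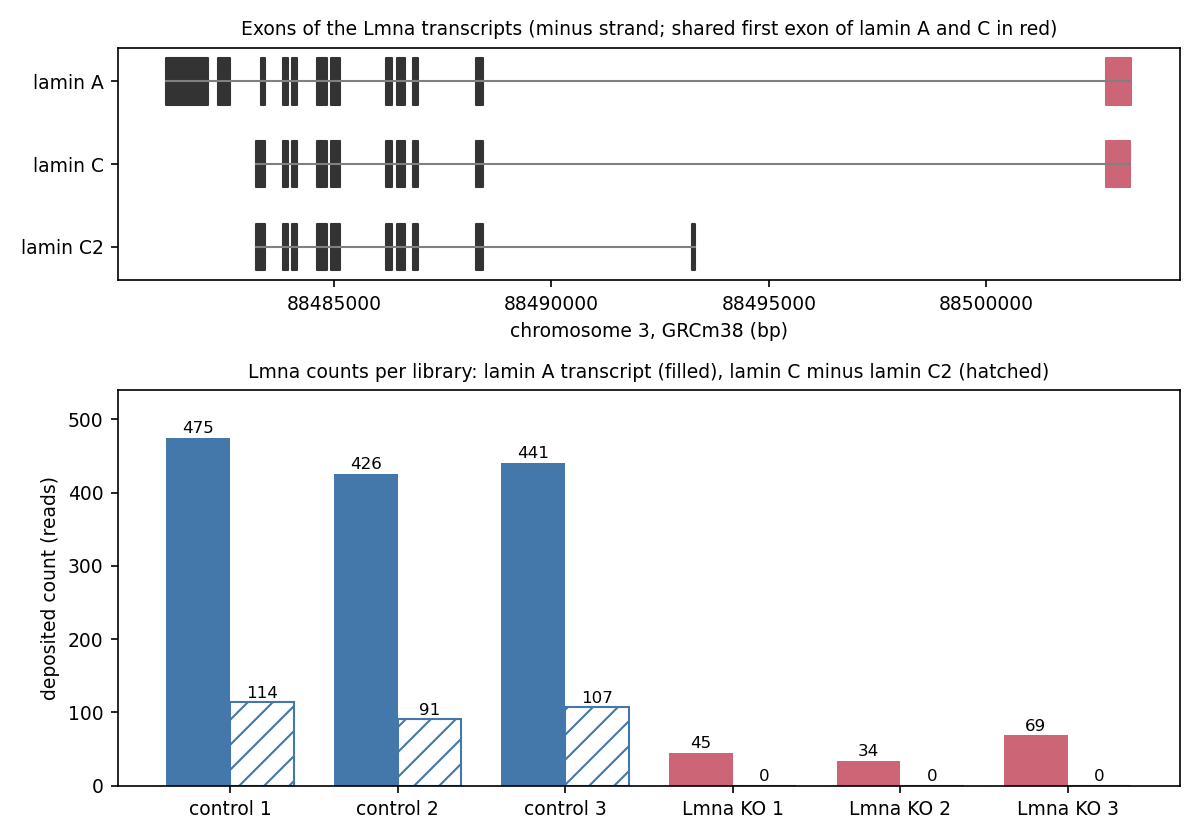
The upper panel maps the exons of the lamin A, C and C2 transcripts on chromosome 3 (GRCm38, bp), with the starting exon of lamins A and C in red. The lower panel gives deposited counts (reads) per library for the lamin A row (filled bars) and for the lamin C row minus the lamin C2 row (hatched bars), which was 0 in all 3 knockout libraries against 91 to 114 in the controls.

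Of the other genes of the nuclear lamina and envelope, 5 rose and 5 fell among 18, all by far less than Lmna. Syne1, which links the nucleus to the cytoskeleton, rose by a log2 fold change of 0.77 (SE 0.11), Sun2, its partner in the inner nuclear membrane, by 0.46 (SE 0.08), and Icmt, which methylates prelamin A, by 0.39 (SE 0.07). The B-type lamins did not pass the test, with 0.06 (SE 0.06) for Lmnb1 and 0.02 (SE 0.07) for Lmnb2, both looked up after their values were seen. With Lmna, 5 of 19 members rose and 6 fell, also when adjusted over the list alone. The list did not stand apart from other genes (camera adjusted p = 0.973), and its median of 0.06 and mean of -0.10 differ in sign.

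Across the genome, 3994 of 14737 genes were higher and 4013 were lower in the knockout libraries (edgeR, adjusted p under 0.05), and 6730 did not pass. Most changes were small: the median absolute log2 fold change of the called genes was 0.49, and 876 genes rose and 740 fell by at least 1 on the log2 scale. The groups did not overlap for 61.2% of genes, where chance gives 10%. The first principal component held 80.2% of the variance and separated the groups. The second held 6.43% and set knockout 1 (22.8) apart from knockouts 2 (-9.48) and 3 (-11.4). The biological coefficient of variation was 6.76%, low enough for small changes to pass the test.

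Among the 10 genes of largest rise, Foxe1, a thyroid and pharyngeal transcription factor on chromosome 4, rose 27.8-fold from 1.25 ± 0.39 to 35.1 ± 5.09 CPM (SE 0.20 on the log2 scale, edgeR adjusted p = 3.67e-09). Vgll2, a transcription cofactor of skeletal muscle and the pharyngeal arches, rose 27.6-fold (log2 SE 0.34). Pax1, active in the pharyngeal pouches and the sclerotome, rose 20.3-fold from 2.67 ± 0.44 to 54.5 ± 18.2 CPM (log2 SE 0.28). The noradrenaline transporter Slc6a2 rose 26.1-fold (log2 SE 0.25). The placental genes Prl2b1 and Ctsj rose 26.3-fold (log2 SE 0.46) and 15.4-fold (log2 SE 0.52). Both have close relatives nearby in the genome, and how reads shared between relatives were counted is not given in the sources used here. Cdhr2 of the brush border, the transporters Slco2b1 and Slc2a2, and the apolipoprotein Apoa4 rose between 11.7-fold and 14.7-fold, with log2 SE values between 0.32 and 0.53. The log2 fold change of Slc2a2 rested partly on single libraries, as 3.55 became 4.38 without control 2 and 2.90 without knockout 1.

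Among the 10 genes of largest fall, Hoxb9, a patterning gene of the trunk, was 32.2-fold lower, from 14.5 ± 0.60 to 0.436 ± 0.280 CPM (log2 SE 0.26, edgeR adjusted p = 2.13e-08), and Hoxa9 12.3-fold lower (log2 SE 0.24). The log2 fold change of Hoxb9 was -5.01, and -5.61 without knockout 1. Mest, an imprinted gene on chromosome 6 at 30733506 to 30748466, was 26.0-fold lower, from 1484 ± 40.6 to 57.1 ± 18.9 CPM (log2 SE 0.17, edgeR adjusted p = 9.52e-10). Plagl1, an imprinted zinc finger gene, was 11.5-fold lower (log2 SE 0.20). The embryonic globin Hbb-bh1 was 12.0-fold lower, from 678 ± 196 to 56.4 ± 23.6 CPM (log2 SE 0.26), and the red cell membrane gene Gypa 11.7-fold lower (log2 SE 0.31). The log2 fold change of Gypa was -3.55, and -4.35 without control 2 and knockout 1. The immune receptor Lilrb4a, which has a close relative, was 14.1-fold lower (log2 SE 0.20). The secreted phosphoprotein Spp1 was 9.51-fold lower (log2 SE 0.11), and the neurofilament gene Nefm 8.21-fold lower (log2 SE 0.28). Lmna is the other of these 10 genes.

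Genes of the extraembryonic endoderm, the tissue that forms the yolk sac lining, had the highest medians of the lists tested. All 13 parietal endoderm genes rose, with a median log2 fold change of 2.22 (camera adjusted p = 5.76e-11). With an estimated correlation the adjusted p was 0.307, and fry gave an adjusted p of 0.00188. The basement membrane genes of this list were among them: Col4a1 rose by 2.69 (SE 0.14) from 887 ± 178 to 5704 ± 829 CPM, Lamc1 by 2.28 (SE 0.12) and Lamb1 by 2.19 (SE 0.12). Thbd, a thrombin receptor, rose by 3.48 (SE 0.18). Of 24 genes of visceral endoderm and liver, 20 rose, 2 fell and 2 did not pass, with a median of 1.52 (camera adjusted p = 7.28e-07). With an estimated correlation the adjusted p was 0.307. Apoa1, a lipoprotein gene, rose by 2.48 (SE 0.18), the fetal serum protein Afp by 1.79 (SE 0.15), the transferrin gene Trf by 2.55 (SE 0.22) and the endocytic receptor Cubn by 2.15 (SE 0.19). The members that fell were Alb (-2.81, SE 0.25) and Ahsg (-1.99, SE 0.41), both serum protein genes of hepatocytes, named after their values were seen. Counts of both lists were equal when adjusted over the list alone. Among the controls, library 2 had the lowest mean log2 CPM of the parietal list, at 6.49 against 7 and 7.06. Among the knockouts, library 1 had the highest mean of the visceral list, at 6.32 against 5.78 and 5.71. Without these libraries 13 parietal and 21 visceral genes rose.

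Epithelial genes rose as well: 16 of 20 passed and none fell, with a median of 0.47 (camera adjusted p = 6.89e-07, but adjusted p = 0.259 with an estimated correlation). Adjusted over the list alone, 18 rose. The tight junction gene Cldn3 rose by 1.74 (SE 0.12), the keratin Krt7 by 1.49 (SE 0.10), the protease inhibitor Spint2 by 0.77 (SE 0.05) and the epithelial splicing factor Esrp1 by 0.75 (SE 0.07). Of 15 definitive endoderm and gut genes, 8 rose and 4 fell, with a median of 0.36 (camera adjusted p = 0.390). Cer1, a secreted inhibitor of early endoderm, fell by 2.14 on the log2 scale (SE 0.18), and Cxcr4 by 0.77 (SE 0.09). Gata6, which extraembryonic endoderm also expresses, rose by 0.89 (SE 0.08). That list shares 6 members with other lists. Of 14 trophoblast genes, 7 rose and 3 fell, with a median of 0.34 (camera adjusted p = 0.447). Rhox6 rose by 2.09 (SE 0.09), whereas Cdx2 and Hand1 were lower, at -1.30 (SE 0.16) and -1.06 (SE 0.16). Without knockout library 1, 5 trophoblast genes fell. Adjusted over the list alone, 8 endoderm genes rose and 4 fell, and 8 trophoblast genes rose and 3 fell. Fry called the trophoblast list higher (adjusted p = 0.0173), but not without control 1 (0.0559), control 2 (0.0759) or control 3 (0.0763), nor without control 2 and knockout 1 together (0.196).

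**Figure D2:**
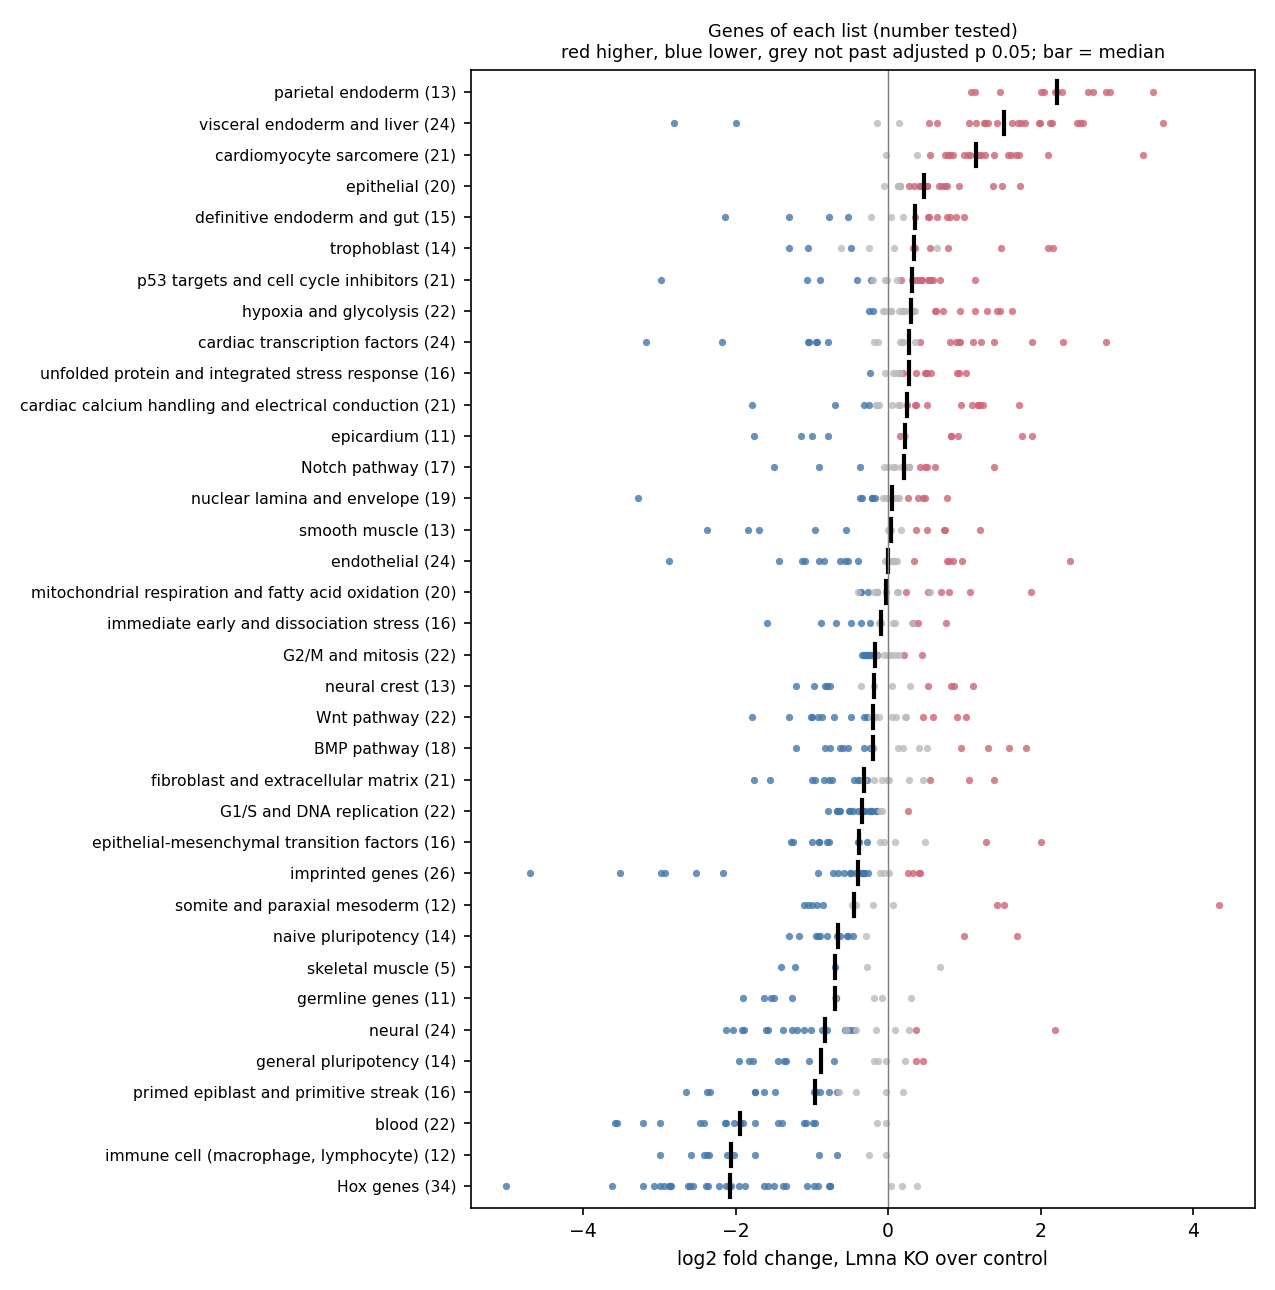
Each row is a gene list with the number of genes tested, and each point is a gene at its log2 fold change, knockout over control (horizontal axis). Red points rose, blue points fell and grey points did not pass edgeR's test, and the black bar is the list's median, from 2.22 for parietal endoderm to -2.07 for the Hox genes.

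Heart muscle genes rose. The sarcomere list as written also holds the secreted peptide genes Nppa and Nppb. Of its 21 genes tested, 19 rose, none fell and 2 did not pass, with a median of 1.16 (camera adjusted p = 5.91e-09), and the counts were equal when adjusted over the list alone. With an estimated correlation the adjusted p was 0.307, and fry gave an adjusted p of 0.00395. The slow myosin Myh7 rose by 1.68 (SE 0.08) from 25.6 ± 1.67 to 82.0 ± 4.65 CPM (edgeR adjusted p = 1.09e-08). The atrial myosin Myh6 rose by 1.61 (SE 0.15), the light chain Myl3 by 2.10 (SE 0.16), Mybpc3 by 1.38 (SE 0.10) and the troponin Tnnt2 by 0.75 (SE 0.13). Of 21 genes of calcium handling and conduction, 11 rose and 4 fell, also over the list alone, with a median of 0.25 (camera adjusted p = 0.0915). That camera call was gained without knockout library 1 (adjusted p = 0.0360). Fry called the list higher (adjusted p = 0.0171), but not without control 1 (0.0692) or control 3 (0.0763). The sodium-calcium exchanger Slc8a1 rose by 1.20 (SE 0.09) and the ryanodine receptor Ryr2 by 1.18 (SE 0.11). The list of cardiac transcription factors, which also holds the growth factor Fgf10, split. Of its 24 genes, 11 rose and 7 fell (13 and 7 when adjusted over the list alone), with a median of 0.28 (camera adjusted p = 0.231). Fry called that list higher on balance (adjusted p = 0.0128), but not without control 1 (0.0692), control 2 (0.0641) or control 3 (0.0763). Nkx2-5 rose by 0.93 (SE 0.14) from 7.88 ± 1.36 to 15.0 ± 1.45 CPM, Gata4 by 0.94 (SE 0.07) and Irx3 by 1.22 (SE 0.09). Foxh1, a Nodal pathway factor, fell by 2.18 on the log2 scale (SE 0.14). Mesp1, the early cardiac mesoderm factor, was named after its value was seen, and fell by 3.17 (SE 0.33).

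The smooth muscle and epicardial lists were mixed, and the skeletal muscle genes that passed all fell. Of 13 smooth muscle genes, 5 rose and 5 fell, also over the list alone. The contractile genes Tagln (-1.69, SE 0.08), Cnn1 (-1.84, SE 0.13) and Acta2 (-0.96, SE 0.07) were lower. The list's median of 0.04 and mean of -0.28 differ in sign (camera adjusted p = 0.539), and fry called it lower on balance (adjusted p = 0.00753). Of 11 epicardial genes, 6 rose and 4 fell, also over the list alone, with a median of 0.22 (camera adjusted p = 0.712). Fry did not call that list (adjusted p = 0.792) except without knockout 1 (0.0289). Sema3d rose by 1.76 (SE 0.15) and Tcf21, shared with the fibroblast list, was lower at -1.76 (SE 0.12). Of 5 skeletal muscle genes tested, 3 were lower, also over the list alone, with a median of -0.69 (camera adjusted p = 0.230), among them Tnnt3 (-1.22, SE 0.22) and Tnni2 (-1.41, SE 0.30). Fry called that list lower (adjusted p = 0.0302), but not without control 1 (0.0815), control 3 (0.0848), knockout 2 (0.101) or knockout 3 (0.129). Acta1 was lower at -0.69 (SE 0.23, edgeR adjusted p = 0.0210). It did not pass without control 1 (adjusted p = 0.0899), control 3 (0.0655), knockout 2 (0.0762) or knockout 3 (0.0816), and the log2 fold change of Acta1 was -1.18 without control 2 and knockout 1.

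Blood genes fell together. Of 22, 20 fell, none rose and 2 did not pass, with a median of -1.95 (camera adjusted p = 1.30e-09), also over the list alone. With an estimated correlation the adjusted p was 0.307, and fry gave an adjusted p of 0.00267. Besides Hbb-bh1, the haematopoietic transcription factor Tal1 was lower at -2.13 (SE 0.16), as were the signalling adaptors Tyrobp (-2.03, SE 0.14) and Fcer1g (-2.42, SE 0.17). The adult alpha globins Hba-a1 and Hba-a2 had equal fold changes of -1.95 (SE 0.18). They are near-identical copies that share reads, so they are not separate evidence, and both were named after their values were seen. Of 12 genes of macrophages and lymphocytes, 5 of them shared with other lists, 10 fell and none rose, with a median of -2.07 (camera adjusted p = 2.50e-05), also over the list alone. With an estimated correlation the adjusted p was 0.307. The complement gene C1qb was lower at -2.58 (SE 0.18). Endothelial genes went both ways, with 6 of 24 risen and 10 fallen, also over the list alone, and a median of -0.01 (camera adjusted p = 0.539). Knockout 1 stood apart, with a mean log2 CPM of 4.32 against 4.08 in each other knockout and 4.33 ± 0.05 in controls. Fry did not call the endothelial list (adjusted p = 0.393) except without knockout 1 (0.0202), or without it and control 2 (0.0134). The VEGF receptor Kdr was lower at -1.12 (SE 0.13), the adhesion molecule Pecam1 at -0.52 (SE 0.07) and Etv2, which specifies blood and endothelial precursors, at -2.87 (SE 0.23). Cdh5, the endothelial cadherin, rose by 0.86 (SE 0.07) and Sox7, which is also expressed in extraembryonic endoderm, by 2.38 (SE 0.15).

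Genes of the undifferentiated state and of the primitive streak fell. Of 14 naive pluripotency genes, 11 fell and 2 rose, with a median of -0.65 (camera adjusted p = 0.00519). With an estimated correlation the adjusted p was 0.313. Nanog fell from 125 ± 3.41 to 66.3 ± 10.7 CPM (log2 fold change -0.92, SE 0.09, edgeR adjusted p = 3.65e-06) and Zfp42 by 1.17 on the log2 scale (SE 0.11). Klf4, also a gene of differentiated epithelia, rose by 1.69 (SE 0.14). Of 14 general pluripotency genes, 8 fell and 2 rose, with a median of -0.88 (camera adjusted p = 0.00639, and adjusted p = 0.307 with an estimated correlation). Pou5f1 fell from 142 ± 4.64 to 55.3 ± 18.3 CPM (log2 fold change -1.36, SE 0.15), and the Nodal co-receptor Tdgf1 by 1.96 (SE 0.13). Of 16 genes of the primed epiblast and primitive streak, 12 fell and none rose, with a median of -0.96 (camera adjusted p = 7.62e-06, and adjusted p = 0.307 with an estimated correlation). Mixl1, Evx1 and Eomes were lower at -2.34 (SE 0.15), -2.38 (SE 0.17) and -1.74 (SE 0.15). Of 11 germline genes, 7 fell and none rose, with a median of -0.70 (camera adjusted p = 0.00823, and adjusted p = 0.307 with an estimated correlation). The RNA-binding gene Dazl was lower at -1.91 (SE 0.25). Knockout 1 lay nearest the controls, with a mean log2 CPM of 3.65 against 3.17 and 3.14 for the streak list, and 1.93 against 1.58 and 1.45 for the germline list. Its Pou5f1 was at 76.4 CPM against 46.6 and 42.9. The counts of these 4 lists were equal when adjusted over the list alone.

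Patterning genes of the trunk and neural genes fell. Of 34 Hox genes tested, 31 fell, none rose and 3 did not pass, also over the list alone. The median was -2.07 (camera adjusted p = 5.76e-11, and adjusted p = 0.259 with an estimated correlation), and fry gave an adjusted p of 0.000825. Besides Hoxb9 and Hoxa9, Hoxd9 was lower at -2.60 (SE 0.16) and Hoxd13 at -2.88 (SE 0.22). Of 24 neural genes, 17 fell and 2 rose, also over the list alone, with a median of -0.83 (camera adjusted p = 0.000365, and adjusted p = 0.307 with an estimated correlation). Tubb3, the neuronal tubulin, fell by 2.13 on the log2 scale (SE 0.12) and Stmn2, a growth cone gene, by 1.58 (SE 0.14). Foxg1, a forebrain factor, rose by 2.19 (SE 0.21) from 2.74 ± 0.29 to 12.5 ± 2.75 CPM. Of 13 neural crest genes, 4 rose and 5 fell (4 and 6 over the list alone), with a median of -0.19 (camera adjusted p = 0.773). Ednrb rose by 0.87 (SE 0.07), and Msx1 was lower at -1.22 (SE 0.10). Of 12 somite and paraxial mesoderm genes, 3 rose, Pax1, Pax9 (1.52, SE 0.19) and Foxc1 (1.43, SE 0.14), and 5 fell, also over the list alone. Its median of -0.45 and mean of 0.11 differ in sign (camera adjusted p = 0.774). The number that fell was 3 with DESeq2, 3 without control 1, control 3 or knockout 1, and 2 without knockout 2. Fry did not call the somite list (adjusted p = 0.792), but did without knockout 1 (0.00435), and without it and control 2 (0.02145).

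**Figure D3:**
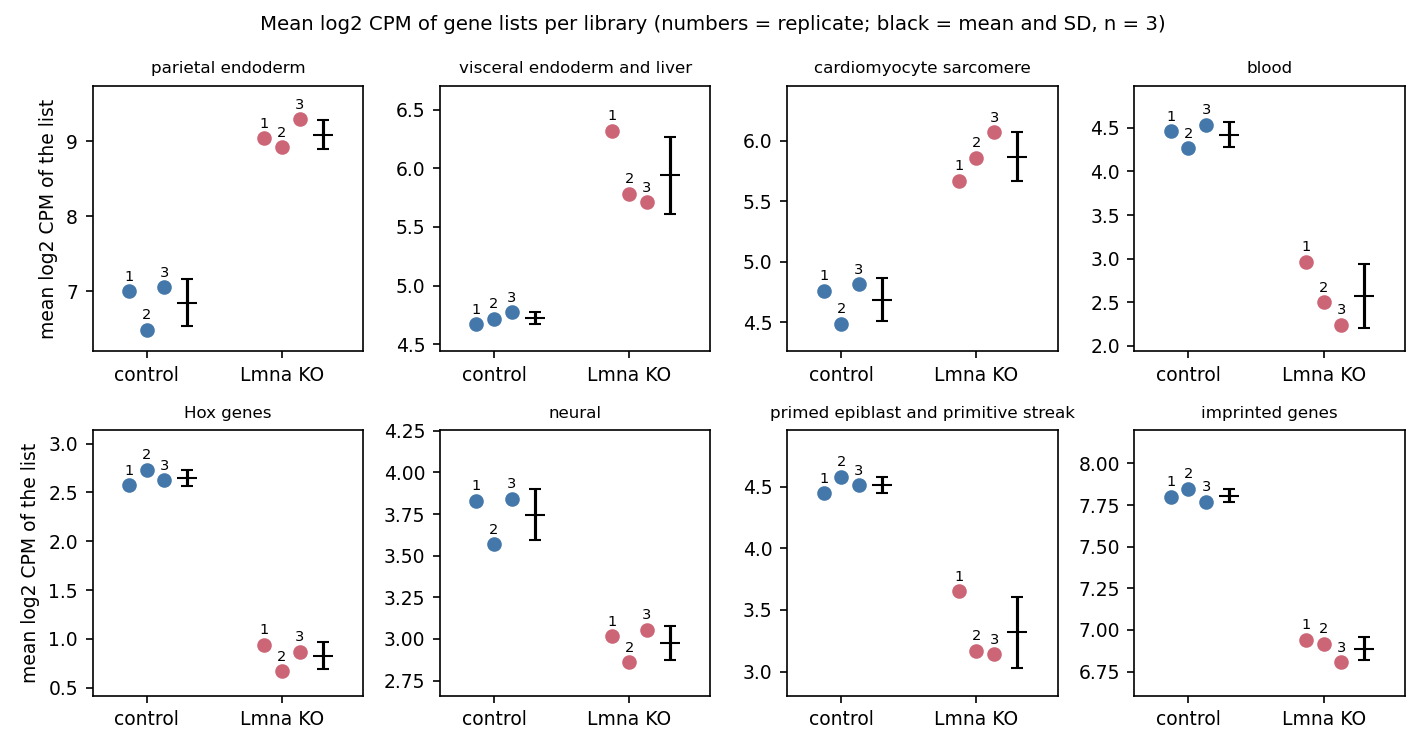
Each panel gives the mean log2 CPM of a gene list (vertical axis) in each of the 6 libraries, numbered by replicate, with the group mean and SD in black (n = 3). The knockout libraries lie above the controls for parietal endoderm (9.08 ± 0.19 against 6.85 ± 0.31), visceral endoderm and sarcomere genes, and below them for blood, Hox, neural, streak and imprinted genes (6.89 ± 0.07 against 7.81 ± 0.04). Panels have separate vertical scales that do not start at 0.

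More mesenchymal genes fell than rose. Of 16 epithelial-mesenchymal transition factors, 10 fell and 2 rose (10 and 3 over the list alone), with a median of -0.39 (camera adjusted p = 0.0121, and adjusted p = 0.307 with an estimated correlation). Vim, the mesenchymal intermediate filament, was lower at -1.25 (SE 0.08), the repressor Zeb2 at -1.28 (SE 0.08) and the cadherin Cdh2 at -0.91 (SE 0.06). Sparc, which is also on the parietal endoderm list, rose by 2.00 (SE 0.13). Of 21 fibroblast and matrix genes, which the feeder cells also express, 11 fell and 3 rose (11 and 4 over the list alone), with a median of -0.32 (camera adjusted p = 0.0650). That call was gained without control 1 (adjusted p = 0.0285), control 3 (0.0286), knockout 1 (0.0313) or knockout 2 (0.0493), and with no low-count filter (0.0478). Without knockout 3, 5 of its genes rose. Tcf21 and Pdgfrb, at -0.84 (SE 0.09), were lower, and Pdgfra rose by 0.55 (SE 0.07).

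Signalling genes moved both ways. Of 22 Wnt pathway genes, 10 fell and 4 rose, with a median of -0.20 (camera adjusted p = 0.0915), and fry called the list lower on balance (adjusted p = 0.000951). The Wnt enhancers Rspo3 and Lgr5 were lower at -1.78 (SE 0.11) and -1.30 (SE 0.12), and Wnt5a at -1.02 (SE 0.07). Of 18 BMP pathway genes, 9 fell and 4 rose. The median was -0.20 and the mean 0.08 (camera adjusted p = 0.365). Fry called the list lower (adjusted p = 0.0297), but not without control 1 (0.0731), knockout 1 (0.709), knockout 2 (0.109) or knockout 3 (0.231), nor without control 2 and knockout 1 together (0.0920). The BMP antagonist Nog rose by 1.80 (SE 0.14), Id4 by 1.59 (SE 0.14), and the receptor decoy Bambi was lower at -0.82 (SE 0.06). Of 17 Notch pathway genes, 7 rose and 3 fell, with a median of 0.21 (camera adjusted p = 0.230). Fry called the list higher (adjusted p = 0.0176), but not without control 1 (0.0692), control 2 (0.0641), control 3 (0.0848) or knockout 3 (0.0591). The ligand Jag2 rose by 1.39 (SE 0.11), and Dll3 was lower at -1.50 (SE 0.23). The counts of these 3 lists were equal when adjusted over the list alone.

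Imprinted genes, which are expressed from only the maternal or the paternal copy, fell more often than they rose. Of 26 tested, 19 fell, 4 rose and 3 did not pass, also over the list alone, with a median of -0.40 (camera adjusted p = 1.54e-05, and adjusted p = 0.259 with an estimated correlation). Fry gave an adjusted p of 0.000951. Besides Mest and Plagl1, the growth inhibitor Cdkn1c on chromosome 7 was lower at -2.98 (SE 0.10), from 175 ± 25.4 to 22.05 ± 1.64 CPM, and Nnat, a membrane protein gene of the brain, at -2.17 (SE 0.11).

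By chromosome, medians of log2 fold change lay close to each other. The difference between a chromosome's median and that of all other genes lay between -0.08 and 0.07 for the autosomes. On the X chromosome, 535 genes had a median of -0.14 against 0.00 elsewhere, a difference of -0.15, with 107 genes higher and 200 lower.

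In the authors' deposited table, 6827 transcript rows were higher and 6617 lower in the knockout at an adjusted p under 0.05. Among the 14737 genes left by the low-count filter, 3450 were higher and 3389 lower in the authors' deposited table. Of these, 3449 and 3384 were called in the same direction by the edgeR test and none in the opposite direction. The authors' deposited table gives a log2 fold change of -3.29 for Lmna, with an adjusted p of 1.55e-75.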

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

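The alternatives that leave out control 2 and knockout 1 together, keep the longest transcript or keep all transcript rows were chosen after the data were seen. Under every alternative for scaling, test, low-count filter, transcript rows and left-out libraries, the counts of genes stayed within 1.5 times the main counts of 3994 higher and 4013 lower. Leaving out 1 library gave between 3412 and 3998 higher and between 3404 and 3908 lower genes. Upper-quartile factors shifted the median of all genes to -0.03 and gave 3724 higher and 4299 lower genes. DESeq2 gave 3446 and 3390, of which 3444 and 3385 were called in the same direction in the main test. Without control 2 and knockout 1, 3884 were higher and 3877 lower, 5 fibroblast genes rose (from 3), and 3 somite genes fell (from 5). Also without these 2 libraries, 4 epithelial-mesenchymal transition genes (from 2) and 1 mitosis gene (from 2) rose, and calcium handling genes gained a camera call (adjusted p = 0.0322). With all transcript rows tested, 4111 genes had at least 1 row that passed as higher and 4087 at least 1 that passed as lower. A minimum absolute log2 fold change of 1 left 876 higher and 740 lower genes, because the threshold itself removes small changes. The fold change of Lmna lay between -3.61 and -3.06 over all alternatives. The X chromosome's difference was -0.11 with genes of a mean CPM of at least 5, and the cause of that move from -0.15 was not tested. With these genes chromosome 13 came close to it, at -0.10 (from -0.08).

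The replicate number as a block gave 4190 higher and 4194 lower genes. Whether the numbers pair the samples stays open. Deviations from the group means correlated across genes at -0.07, 0.12 and 0.06 for numbers 1, 2 and 3. Control 2 and knockout 2 correlated best with each other, but not every sample correlated best with its own number. No camera call changed under the replicate block except that of the fibroblast list (adjusted p = 0.0470, from 0.0650). Under the block 7 genes of respiration and fatty acid oxidation fell, from 4, and 5 fibroblast genes rose, from 3. The block ended the fry call of calcium handling (adjusted p = 0.0503), Notch (0.0503), BMP (0.139) and trophoblast genes (0.189). It gained that of definitive endoderm (0.0197, from 0.0618) and somite genes (0.0383, from 0.792).

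With camera, 18 of 36 lists passed at the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.259. At an unadjusted p under 0.05, 4 lists passed with an estimated correlation. Fry, which does not compare a list with other genes, called 27 at an adjusted p under 0.05. The fry call of 7 lists was lost and that of 6 gained under at least 1 alternative, and 23 lists kept theirs. Those not given elsewhere are a loss for hypoxia genes without control 1 (adjusted p = 0.0507, from 0.0104), and gains for fibroblast genes with no low-count filter (0.0443, from 0.0649), for immediate early genes with upper-quartile factors (0.0421, from 0.0618), and for definitive endoderm without knockout 2 (0.0302) or with no scaling factors (0.0489). Among list counts, 18 of 1071 values moved by over 1.5 times, all of them counts of 5 or fewer members in the main test. Besides the estimated correlation, camera lost a call only for mitosis genes (adjusted p = 0.0698 without knockout 3). Of the 2652 values of named genes, 4 lost the call, all of Acta1, and 0 reversed. Most of these genes were named for a small adjusted p or a large fold change, so few could have lost it. No list median and no named gene changed sign under the other scalings. Those scalings moved the median of all genes to -0.03 at lowest, so hardly any sign could have changed. Low counts limit what can be seen: genes near 1 CPM rest on about 10 reads per library.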

Other observations

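Tests on library scaling, on other cell types, on imprinting and on mixed cells were chosen after the results were seen. Those on GC content and length, on splits of the samples, on chromosomes and on gene density were set before. Imprinted genes other than Mest, Plagl1, Nnat and Cdkn1c were picked after their values were seen.

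Genes of DNA replication were modestly lower in the knockout libraries. Of 22 genes of the G1/S list, 19 fell and 1 rose, with a median of -0.34 (camera adjusted p = 2.51e-06, and adjusted p = 0.307 with an estimated correlation). Dhfr, Pcna and Pola1 were lower at -0.63 (SE 0.06), -0.67 (SE 0.06) and -0.64 (SE 0.06). Of 22 mitosis genes, 14 fell and 2 rose (15 and 3 over the list alone), with a median of -0.17. Their camera adjusted p was 0.0244, which was 0.0698 without knockout 3 and 0.313 with an estimated correlation. Without control 1, 1 mitosis gene rose. Nusap1 and Birc5 were lower at -0.31 (SE 0.05) and -0.34 (SE 0.06), whereas Aurkb rose by 0.44 (SE 0.07). Of 21 p53 targets and cell cycle inhibitors, 12 rose and 5 fell, with a median of 0.32 (camera adjusted p = 0.0630, and 0.0496 with no low-count filter). Their mean was only 0.02, so the list hardly moved on average, although fry called it higher (adjusted p = 0.00347). The inhibitor Cdkn1a rose by 1.14 (SE 0.06), from 161 ± 1.73 to 355 ± 26.0 CPM, and Ei24 and Phlda3 by 0.59 (SE 0.06) and 0.68 (SE 0.08), while Cdkn1c was the deepest fall of that list.

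In lists of low oxygen and of secretory stress, more genes rose than fell. Of 22 hypoxia and glycolysis genes, 10 rose, 2 fell and 10 did not pass, with a median of 0.30 (camera adjusted p = 0.00106, and adjusted p = 0.408 with an estimated correlation). The collagen-modifying enzyme P4ha1 rose by 1.30 (SE 0.09), the oxygen sensor Egln3 by 1.14 (SE 0.08), the angiogenic factor Vegfa by 0.94 (SE 0.07) and Ndrg1 by 1.46 (SE 0.12). The number that fell was 1 without control 3 or knockout 3 and 0 without knockout 2 (edgeR). Of 16 genes of the unfolded protein and integrated stress response, 9 rose, 1 fell and 6 did not pass, with a median of 0.28 (camera adjusted p = 0.00369, and adjusted p = 0.307 with an estimated correlation). Ddit4 rose by 0.93 (SE 0.07) and Xbp1 by 0.51 (SE 0.08). Of 16 immediate early genes, 3 rose and 6 fell, with a median of -0.10 (camera adjusted p = 0.339), and Egr1 was lower at -0.68 (SE 0.09). Of 20 nuclear-encoded genes of mitochondrial respiration and fatty acid oxidation, 6 rose and 4 fell (camera adjusted p = 0.809), with a median of -0.02 and a mean of 0.19, and 7 fell with upper-quartile factors. Cox6a2 and Fabp3, both abundant in heart muscle, rose by 1.87 (SE 0.20) and 1.07 (SE 0.14). Over the list alone, the counts of each list of these 2 paragraphs were equal except for mitosis. The 13 mitochondrially encoded genes of the remaining list were not in the table.

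The rise of extraembryonic endoderm genes had a pooled median log2 fold change of 1.79 over 37 members. The 3 other scalings of the libraries left the pooled median at 1.77 or above. They gave all genes a median of -0.03 at lowest, so that test could hardly have come out otherwise and says little on scaling. Against GC content and transcript length (known for 100% of members) as the whole cause, removing the trend of fold change on them left the pooled median at 1.89. A lower share of a main cell type would lower its own markers and raise those of all other types alike. Of 8 other cell type lists, 2 (blood and neural) had a median below -0.5 with most members lower. Lists outside these 8 also did, among them those of macrophages and lymphocytes (-2.07), the primitive streak (-0.96) and skeletal muscle (-0.69). The pluripotency and germline lists did so too. These falls do not decide, since blood, neural or other such cells could themselves be the lost share. A larger share of yolk sac-type endoderm in the knockout embryoid bodies, or higher expression in the same cells, may both apply, which bulk RNA does not separate. A difference between the cell clones used would be confounded with genotype.

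Imprinted genes fell, and loss of methylation at imprinting control regions would instead raise H19 and the paternally expressed genes whose control region is methylated on the maternal copy, but of 11 such genes past the threshold 0 rose. A gain of methylation there is a hypothesis that also predicts rises of Igf2, Dlk1 and Igf2r, and 3 of these 3 rose, with Igf2 at 0.33 (SE 0.07) beside H19 at -2.52 (SE 0.24), and Dlk1 at 0.42 (SE 0.08) beside Meg3 at -0.34 (SE 0.07). These are too few to decide, as the values had been seen and the falls prompted the hypothesis. The Kcnq1ot1 domain goes against it, since Cdkn1c (-2.98) and Phlda2 (-2.93) fell where a rise was predicted, and Kcnq1ot1 was at -0.05 (SE 0.14). Loss of the cells that express these genes also stays open, since the imprinted genes that fell had a median of -0.58 and no list says which cells express them, and a difference between the clones used would be confounded with genotype.

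The remaining Lmna reads of the knockout libraries did not look like those of mixed-in unedited cells. Control or feeder cells making up the 14.3% of lamin C2 reads would make the lamin C row exceed the lamin C2 row by 48.2 reads over the 3 libraries. The excess was 0 (exact Poisson p = 1.14e-21, one-sided). That p covers counting error only, takes reads as independent and takes the excess as a direct count of starting-exon reads. Reads of lamin C2's own first exon would lower the excess. Library by library, an excess of 14.84, 11.13 and 22.25 reads was to be expected, and each had 0. Transcripts that start downstream of the starting exon of lamins A and C, or an allele that lacks that exon, are possible explanations that the table does not tell apart.

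For the counts of changed genes, the 10 ways to split 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 8007 genes, and 1 of the 10 splits, the real one, gave as many. The highest other split gave 0 genes (edgeR), or 254 at an unadjusted p under 0.05. Every other split mixes libraries of both groups, so the group difference widens the spread within each side. Low counts there were bound to follow and are no separate evidence. A chromosome held in 2 copies and gained or lost in every knockout cell would shift its median by about 0.58 or -1. The autosomes differed by between -0.08 and 0.07. The largest shift was -0.148, on the X chromosome, for which those 2 values hold only if control cells have 2 copies. A change in some of the cells, or of part of a chromosome, would shift a median less and stays open.

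Lamins A and C anchor gene-poor chromatin at the nuclear edge, so a hypothesis was that genes in gene-poor surroundings rise without them. The medians of the genes tested went the other way, but they do not decide the hypothesis. Genes below the low-count filter were not tested, and bulk RNA does not separate changed expression from a changed share of cell types. Genes were parted into 4 equal classes by the number of protein-coding genes within 500 kb on either side. The gene-poorest class (0 to 8) had a median log2 fold change of -0.03, and the gene-richest (26 to 72) a median of 0.05. The difference of -0.0812 lay outside the range of 95% of 1000 shifts of the values along the genome (-0.0347 to 0.0363). In the gene-poorest class 26.7% of genes were higher and 30.9% lower, against 29.1% and 21.6% in the gene-richest.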
